A study of Homo sapiens with 3 samples.

How the data were processed

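RNA of LS174T cells with an inducible Hes1 was compared on 3 two-colour arrays, 1 each for IL-22, doxycycline-induced Hes1 and both. Per the labels, control RNA was labelled with Cy5 and treated RNA with Cy3 on every array, after amplification, and no array had the dyes swapped. The labels give each condition 1 culture, grown and harvested separately, and they do not say whether the control RNA of the arrays came from one preparation. The direction of every ratio, treated over control, follows from these dyes.

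The scanner tables deposited by the authors hold the intensity of each spot in both channels, with control RNA read at 635 nm and treated RNA at 532 nm per the file headers. These intensities had not been normalized. The authors also deposited a value table on a log2 scale, whose making is not given in the sources used here. Set against the scanner tables, its values followed log2 of treated over control after subtraction of the blank spots, plus 1 constant per array (-0.90, -0.97 and -0.65 for IL-22, Hes1 and both). Its array medians were 0, 0 and 0, and 2545, 2609 and 2421 probes had no value. It was used as an alternative.

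Spot medians were corrected with normexp at an offset of 50 without the local background, because on a log scale the local background of a spot rose with the signal of that spot (correlations across probes of 0.87 to 0.98). Loess was then fitted within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0. Spots that the scanner software marked as poor on any array were left out (3, 7 and 6 probes). No spot was saturated. Each probe had 1 spot, so no probes were averaged. A probe counted as above background in a channel when its signal passed the mean plus 2 SD of the 96 negative-control spots of that channel. The limits were 22.7, 21.3 and 22.3 in the control channel and 101, 97.3 and 88.1 in the treated channel, on the IL-22, Hes1 and combined arrays. Medians of the probe signals were 61, 57 and 55 in the control channel and 163, 162 and 136 in the treated channel.

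Single treatments were read from their own array, among probes above background in at least 1 channel. A second estimate came from the combined array minus the other single array. Its own counts were taken among probes above background in the treated channel of at least 1 of those arrays. For counts in both estimates and for named probes, only the background condition of the first estimate was asked. The second estimate shares no array with the first. The dye effect of a probe cancels in this difference only if that effect was equal on the arrays. The control RNA does so only as far as it was alike on the arrays, whose control channels differed with SDs of 0.10 to 0.14. The departure from additivity was the combined log2 ratio minus both single ones. No test was run. A fit of all arrays that assumes additivity has 1 residual degree of freedom, made of the departure itself, and was not used. Counts are of probes at least 2-fold higher or lower (log2 of 1), with 1.5-fold (0.585) asked of the second estimate. Where a probe was not above background in one of the channels compared, no fold was given.

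Named probes followed a rule written before the data were examined, as were the thresholds, the counts for each comparison and the alternatives not marked as added. The counts of probes in both estimates and of probes against each single treatment, the limit for background and the choice not to subtract the local background were set after the data were seen. It took the 12 highest and 12 lowest log2 ratios of each comparison (6 for the departure) above background and not marked as poor. For the single treatments the second estimate also had to have the same sign and at least 1.5-fold. The rule asked for gene symbols, which the files do not pair with the probes. By accession, 1 of the 24460 probes matched the reference table of gene names (assembly GRCh38.p14), and its condition on symbols was dropped. The first 2 probes per direction are printed. Lists of genes fixed beforehand, and the HES1 and REG genes, were not analysed for the same reason.

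The normalization was tested on simulated data with probes of known change. On the IL-22 array, a simulated log2 change of 1.5 was counted as at least 2-fold for 94% of 50 probes and one of 2.5 for 100%, with a median fitted value of 1.31 for the former. On the combined array the share at 1.5 was 76%. No unchanged probe passed. Only bright spots were counted in these shares. The simulated noise had the spread of the bulk of the log2 ratios, and probes had no dye effect of their own. The simulation therefore gives no rate of false calls. The overlap of comparisons that share controls was simulated 100 times with the spread seen between control channels. Alternatives were no background correction, an offset of 16, median centring, the authors' deposited values, no filter on dim probes, a filter on both channels, and thresholds of 1.5-fold and 3-fold. Subtraction of the local background was added after the data were seen. Tables were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.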

Results

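Gene expression was measured in LS174T cells, a line derived from a human colon carcinoma, that carried a tetracycline-inducible Hes1. Hes1 is a transcriptional repressor of the Notch pathway, and interleukin-22 (IL-22) is a cytokine that acts on epithelial cells. The labels describe 3 treatments of 24 h: IL-22 at 20 ng/ml, doxycycline at 100 ng/ml to switch on Hes1, and both together. Each treatment was hybridised on 1 array, with RNA of untreated cells in Cy5 and RNA of treated cells in Cy3. The series' title sets out the question of how the cells respond to IL-22, to forced Hes1, and to IL-22 under forced Hes1. With 1 array per treatment there was no replicate check and no test, no p-value was computed, and the number of arrays limits the precision. Counts therefore describe these arrays.

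The arrays held 24460 probes. Signals stood above the negative controls in at least 1 channel for 79.0% of probes on the IL-22 array, 78.0% on the Hes1 array and 76.0% on the combined array. The files pair no gene with 24459 of these probes, which are given by their identifiers. The probe of 1 gene could be named by its accession: KRT8, which encodes an epithelial keratin. Its log2 ratio of treated to control was -0.48 with IL-22, -0.33 with Hes1 and 0.07 with both, the last being -0.14 in the authors' deposited values. Under median centring the values for IL-22 and Hes1 were -0.26 and -0.13, and with the local background subtracted -0.28 and -0.11. In the authors' deposited values they were further from 0, at -0.62 and -0.52. The HES1 transcript itself and the REG genes were not analysed here, so the induction of Hes1 was not checked. No array held doxycycline-treated cells without the inducible Hes1. An effect of doxycycline itself therefore cannot be told apart from one of Hes1, and Hes1 below stands for the doxycycline treatment.

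The reference for the treated samples was the untreated RNA, which was on every array. The log2 control signals of different arrays differed with an SD of 0.11 between the IL-22 and Hes1 arrays, 0.14 between the IL-22 and combined arrays, and 0.10 between the Hes1 and combined arrays. At least a 2-fold difference was seen for 1, 0 and 0 probes in these pairs. The treated channels differed by at least 2-fold for 37, 398 and 181 probes in the same pairs.

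With IL-22 alone, the probe H200000271 was 18.8-fold higher than in untreated cells (log2 ratio 4.23), with a treated signal of 10051 against a control signal of 258. The probe H200000879 was also higher, with a treated signal of 745 against a control signal of 21 that was not above background. Its log2 ratio depended on the correction, from 2.54 with the local background subtracted to 6.14 in the authors' deposited values. A second estimate of the IL-22 effect, the combined array minus the Hes1 array, does not use the IL-22 array. The dye effect of a probe cancels in this estimate if that effect was equal on those arrays. In the second estimate, H200000271 was higher by 4.81 on the log2 scale. H200000879 was also higher, with no fold given because its treated signal on the Hes1 array was not above background. In all, 7 probes were at least 2-fold higher with IL-22 alone and at least 1.5-fold higher in the second estimate. Leaving out H200000879, their log2 ratios ran from 1.10 to 4.23 with IL-22 alone and from 1.07 to 4.81 in the second estimate. The authors' deposited values gave 29 such probes and local background subtraction gave 66, each with 6 of the 7 among them.

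No probe was at least 2-fold lower with IL-22 in the first estimate and at least 1.5-fold lower in the second. Among probes at least 1.5-fold lower in the second estimate, the lowest on the IL-22 array were DHsGV10004900, with log2 ratios of -0.68 and -0.77, and H200003125, with -0.67 and -0.75. With the local background subtracted, these second estimates turned to 0.27 and 0.35. Before normalization, the control signal of H200003125 was 926, 516 and 684 on the IL-22, Hes1 and combined arrays. The control may therefore not cancel in the second estimates of this probe. Without the second estimate the IL-22 array counted 36 probes at least 2-fold higher and 10 at least 2-fold lower, among 19298 probes above background. The median log2 ratio of the 36 was 1.20 on that array and 0.07 in the second estimate, and 29 of them were below 1.5-fold there. Over all probes above background on the IL-22 array, 2.90% were at least 1.5-fold higher in the second estimate. Across probes, which are not independent replicates, the estimates had a correlation of 0.01. With loess replaced by median centring the IL-22 array counted 153 probes higher and 9 lower, so that 94.4% were higher in place of 78.3%.

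**Figure D1:**
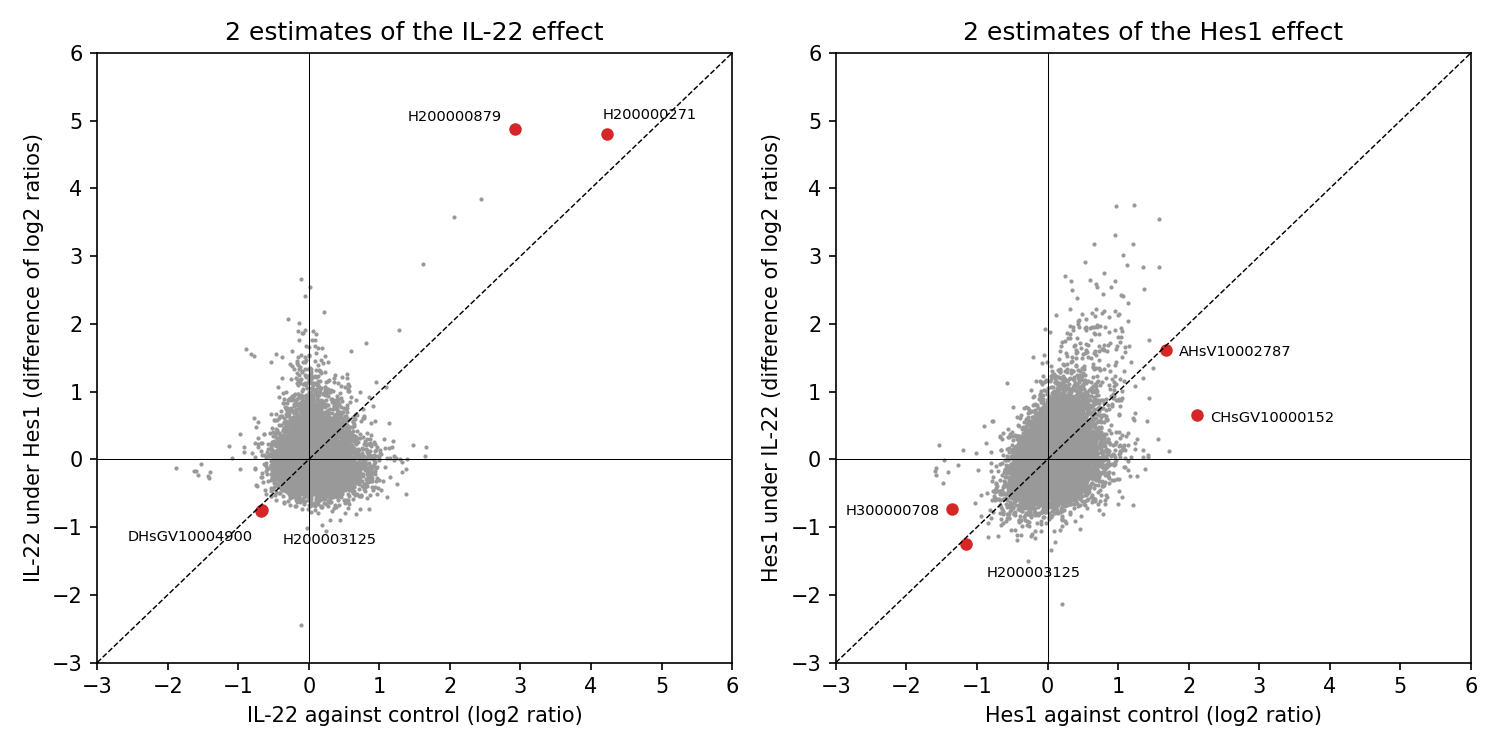
Each grey point is 1 probe, with the log2 ratio of treated to untreated cells on the x axis and the difference of log2 ratios between the combined array and the other single-treatment array on the y axis, for IL-22 (left) and Hes1 (right). Red points are the probes named for that comparison and the dashed line marks equal values; H200000271 lies at 4.23 and 4.81 on the left, and AHsV10002787 at 1.68 and 1.62 on the right.

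On the Hes1 array, 85 probes were at least 2-fold higher and 13 at least 2-fold lower than in untreated cells, among 19079 above background. These counts exceeded those for IL-22 alone, but with the local background subtracted IL-22 had 270 higher against 175 for Hes1, and at 3-fold IL-22 had 7 higher against 3. The second estimate was the combined array minus the IL-22 array. Over all probes above background on the Hes1 array, it was at least 1.5-fold higher for 5.36% and lower for 2.05%. It was at least 1.5-fold the same way for 43 of the 85 and for 3 of the 13. Among these, AHsV10002787 was 3.20-fold higher (log2 ratio 1.68), with a second estimate of 1.62. The probe CHsGV10000152 had the highest log2 ratio, 2.12, with a second estimate of 0.65, and its ratio on the IL-22 array was 1.66. This second estimate was below 1.5-fold under median centring (0.52), in the authors' deposited values (0.58) and with the local background subtracted (0.45). Among the lower probes, H300000708 had log2 ratios of -1.35 and -0.73 in the estimates, and H200003125 had -1.16 and -1.25. Under median centring the ratio of H200003125 on the Hes1 array was -0.89, short of 2-fold.

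The 43 probes higher in both estimates had a median log2 ratio of 1.10 with Hes1 alone, 0.36 with IL-22 alone and 2.02 with both treatments. The last value is partly set by the choice of the probes, since the second estimate contains the combined array. The second estimate of these probes had a median of 1.62. Their median for IL-22 under Hes1 was 0.83, and 18 of them were at least 2-fold higher there. A shift of the combined array alone would raise both differences, so the second estimate cannot tell an effect of Hes1 from such a shift. The remaining 42 of the 85 were below 1.5-fold in the second estimate. The authors' deposited values gave 224 probes higher in both estimates, 36 of them among the 43. Across probes, the estimates of the Hes1 effect had a correlation of 0.36.

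Most probes past 2-fold on the IL-22 array were also past it on the Hes1 array. Among 18157 probes above background on all arrays, 35 were higher with IL-22, 83 with Hes1 and 27 on both of these arrays, where independent lists would share 0.160, and all 10 that were lower with IL-22 were also lower with Hes1, where independent lists would share 0.00716. Unchanged samples were simulated against one control with the spread seen between control channels, which is too narrow to reach 2-fold and so gives no value for the overlap. Part of the overlap may come from the control. The correlation of log2 ratios across probes was 0.76, and the covariance was 0.0451 against a simulated 0.00675. The simulated correlation was 0.50 by construction, since treated and control values were given equal spread, and it is no yardstick for a shared control. The simulated covariance rests on differences between control channels, which leave out what these channels share. A dye effect of a probe enters every array in the same direction here, since no array had the dyes swapped. The excess of covariance is therefore not a measure of a shared response. For IL-22 against the combined array the correlation was 0.49, and the covariance was 0.0451 against a simulated 0.00674. For Hes1 against the combined array the correlation was 0.75, and the covariance was 0.0768 against a simulated 0.00673.

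IL-22 together with Hes1 gave the most probes past 2-fold, 501 higher and 44 lower among 18569 above background. The SD of the log2 ratios on that array was 1.54 times the larger of the others, and the treated signal of its Positive Control 2 spots was 57.2% of the mean on the other arrays. The probes H200000271 and H200000879 were again highest. H200000271 was 47.0-fold higher than in untreated cells, and H200000879 was 28.7-fold higher (log2 ratio 4.84). The latter depended on the correction of its dim control signal, its log2 ratio being 4.27 with the local background subtracted, 5.77 without background correction and 6.65 in the authors' deposited values. The lowest ratios were those of H200009307 and H200003125. H200009307 was 4.75-fold lower (log2 ratio -2.25, and -3.41 in the authors' deposited values), with a treated signal of 115 against 727 on the IL-22 array and 881 on the Hes1 array, and control signals between 341 and 401. H200003125 was 3.77-fold lower (log2 ratio -1.91, with -1.31 under local background subtraction and -2.37 in the authors' deposited values). Of the 501 higher probes, 28 were at least 2-fold higher with IL-22 alone and 74 with Hes1 alone. Of the 44 lower probes, 9 were at least 2-fold lower with IL-22 alone and 12 with Hes1 alone. The authors' deposited values gave 1243 higher and 302 lower, a share of 80.5% higher in place of 91.9%. At an offset of 16 in place of 50 the counts were 769 and 85.

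**Figure D2:**
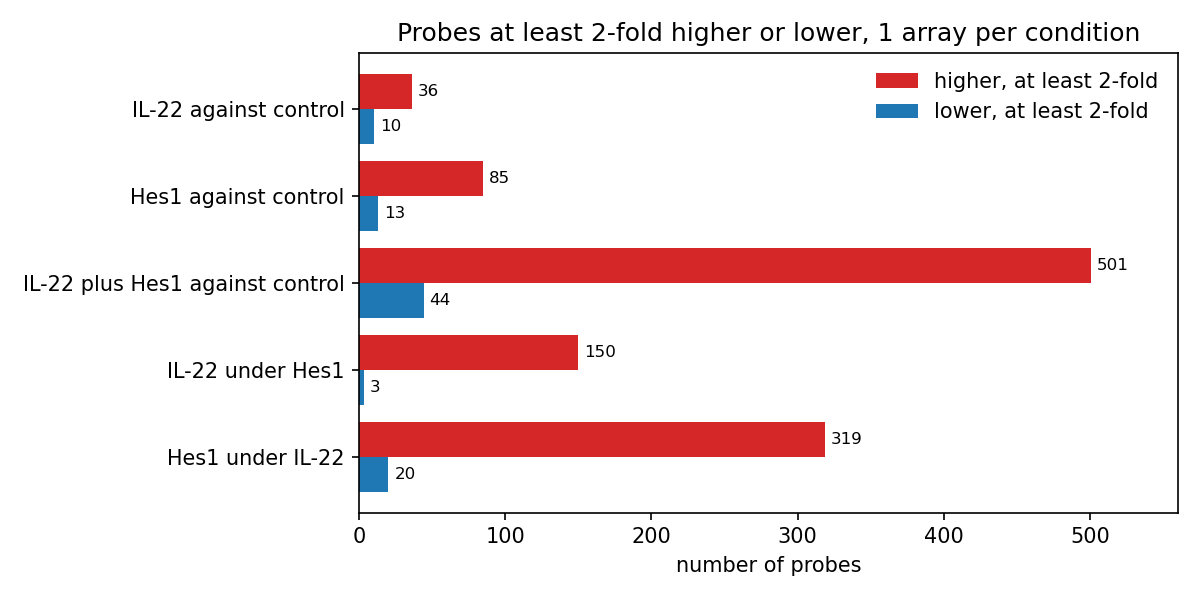
Bars give the number of probes at least 2-fold higher (red) or lower (blue) in each comparison, with the number on the x axis and the comparison on the y axis. The combined treatment stands at 501 higher and 44 lower, and IL-22 alone at 36 higher and 10 lower.

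The effect of adding 1 treatment to the other was read from differences between arrays. In these the dye effect and the control RNA cancel only if they were alike on the arrays. Positive Control 2 spots had mean log2 ratios, after blank subtraction, of 0.70, 0.71 and -0.01 on the IL-22, Hes1 and combined arrays. Equal dye effects on the combined array were therefore not shown. Under Hes1, 150 probes were at least 2-fold higher with IL-22 than without it and 3 were at least 2-fold lower. Under IL-22, 319 were higher with Hes1 and 20 lower. In the authors' deposited values these counts were 518 and 64 for IL-22, and 846 and 207 for Hes1. With the local background subtracted they were 308 and 92 for IL-22, a share higher of 77.0% in place of 98.0%, and 371 and 222 for Hes1, a share of 62.6% in place of 94.1%. The 150 probes had a median log2 ratio of 0.04 with IL-22 alone, where 7 were at least 2-fold higher, and of 0.46 with Hes1 alone. A set of 138 probes was at least 2-fold higher after both treatments than after either one, and 2 were at least 2-fold lower. The count against both single treatments was added after the values were seen, and it rests on 1 treated sample, that of the combined array. The medians of the 138 were 0.03 with IL-22, 0.51 with Hes1 and 1.81 with both. These medians, and those of the 150, are partly set by the choice of probes on the same arrays. In the authors' deposited values 427 probes met the same condition, 127 of them among the 138.

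The departure of the combined log2 ratio from the sum of the single ones was described over 16379 probes above background in both channels of every array. It was at least 1 for 153 probes, of which 17 were at or below 0 on the combined array, and at most -1 for 111. H300004589 had log2 ratios of 0.02 with IL-22, 1.22 with Hes1 and 3.77 with both, a departure of 2.53, which was 1.99 with the local background subtracted. Under that subtraction its ratios with Hes1 and with both were 0.88 and 2.78, and in the authors' deposited values they were 1.74 and 4.5. AHsV10000845 had -0.89, 0.66 and 2.28, a departure of 2.52. H200009307 had -0.11, 0.20 and -2.25, a departure of -2.33, which was -3.35 in the authors' deposited values. For opHsV0400010258 the values were 1.37, 1.21 and 0.70, a departure of -1.88. The departure keeps the dye effect of a probe with its sign turned. The 111 lower probes had a median of 0.79 with IL-22, 0.72 with Hes1 and 0.32 with both. Under median centring the counts were 82 and 752, so that 9.83% were higher in place of 58.0%.

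**Figure D3:**
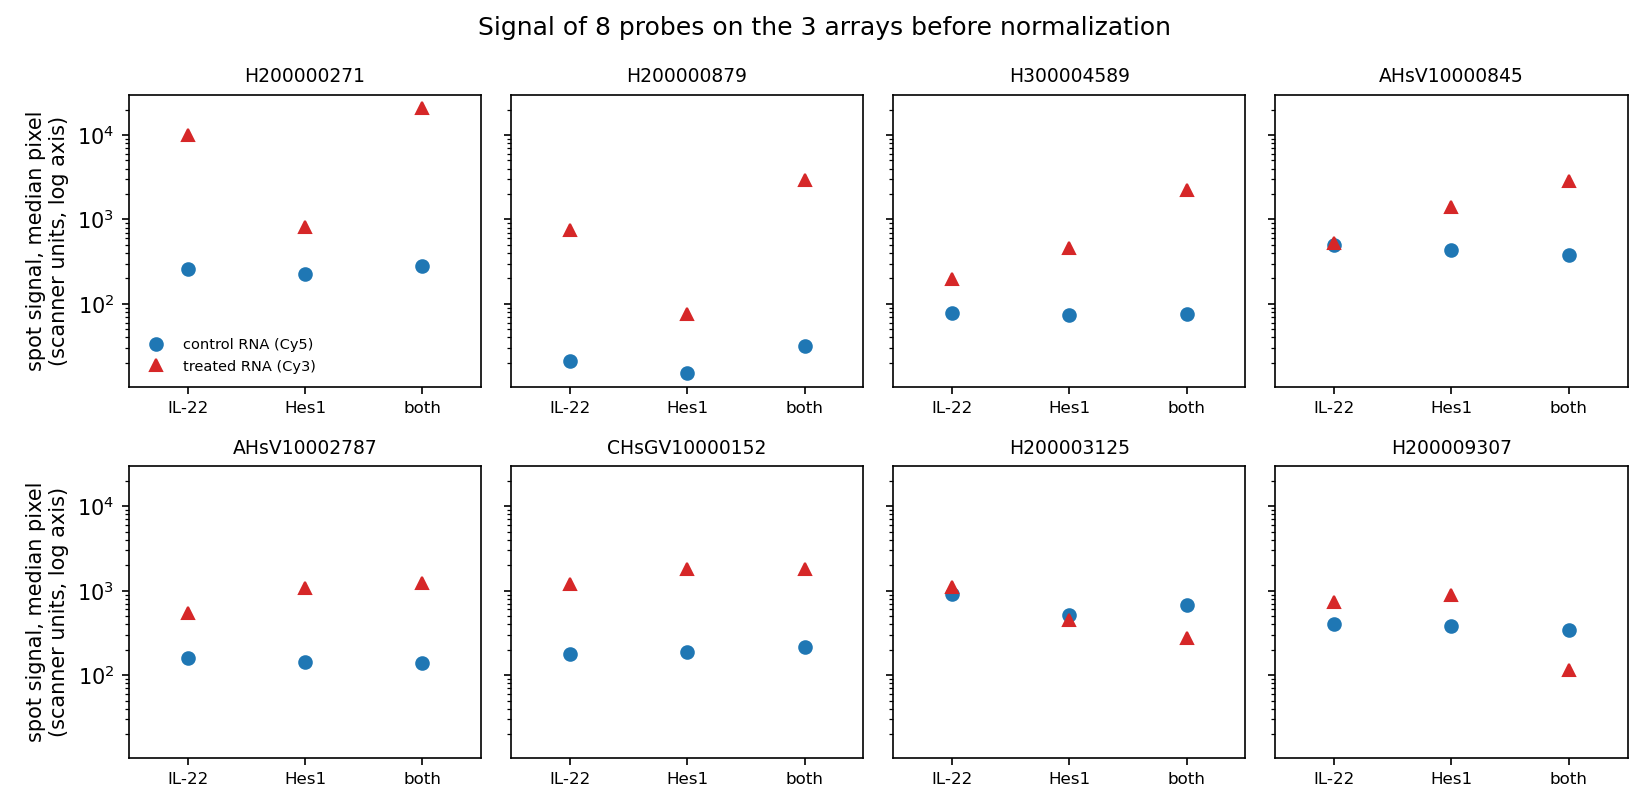
Each panel is 1 probe, with the array on the x axis and the median pixel signal of its spot, before normalization, on a log y axis in scanner units. Circles are control RNA and triangles are treated RNA; the treated signal of H300004589 was 196 with IL-22, 457 with Hes1 and 2234 with both, while its control signal stayed between 73 and 79.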

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

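All tests of explanations in this part, and the bounds that decide them, were chosen after the results were seen, and those on slide noise and on scale were recast after a first version had been computed. The effect of a treatment alone and its effect in the presence of the other went opposite ways, by at least 1.5-fold each, for 8 probes with IL-22 and 12 probes with Hes1. The difference was not tested, and the effect alone keeps the dye effect of each probe. A signal was also present in spots that hold no probe compared here, though they enter the limit for background. The 24 spots of Negative Control 4 had mean control-channel signals of 20.8, 19.1 and 20.0 on the IL-22, Hes1 and combined arrays, above the blank spots at 14.5, 12.9 and 12.4.

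The log2 ratios of the combined array were wider than those of the other arrays, with an SD of 0.40 against 0.23 for IL-22 and 0.26 for Hes1 over probes above background on all arrays. Noise of dim probes would fade with brightness, but the SD was still 1.51 times the larger of the others among the brightest 25% of probes. A noisier slide or scan would widen both control-channel differences with that array, and of these the smaller was 0.933 times and the larger 1.28 times the difference without it. Split by array, the control-channel SD was 0.10 on the IL-22 array, 0.04 on the Hes1 array and 0.09 on the combined array, which speaks against slide noise in that channel as the whole cause. The labelling or quality of the treated RNA on that array stays open: Positive Control 2 spots had 57.2% of their mean treated signal on the other arrays, and 93.6% in the control channel, while Positive Control 1 spots had 82.8% and 98.0%. With 1 treated sample, this and a wider response to both treatments cannot be told apart.

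A set of 37 probes was past 2-fold in the same direction on the IL-22 and the Hes1 array. Were both treatments to act and add up, the combined log2 ratio would equal the sum, but its median was 0.526 of the sum, with quartiles of 0.468 and 0.572. A dye or control effect common to the arrays would leave the ratio alike on each, and the median was 1.05 times the mean of the single ratios, with quartiles of 0.935 and 1.14. A candidate explanation for these probes is therefore the dye or the control rather than the treatments. A response that either treatment brings to its full size would give the same values and was not tested.

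For 153 probes the combined log2 ratio was above the sum of the single ones by at least 1. Were the dye effect the only cause of this departure, the combined ratios would be negative. Their median was 1.35, with quartiles of 0.79 and 1.90. A negative dye effect on top of a response was not excluded and could carry probes past 1. The departures of the 153 had a median of 1.21, with a lower quartile of 1.10. For the 17 probes at or below 0 on the combined array, however, the combined ratio was 0.944 times the mean of the single ones (median, quartiles 0.604 and 1.11), as a dye effect would give. The choice of these probes by combined ratio and departure caps this value, so it does not decide for a dye effect. The offset, which compresses low ratios, could inflate a departure. In the authors' deposited values, which carry no offset, 96.1% of the 153 (147 probes) kept a departure of at least 1. Those values spread more widely, with an SD on the combined array of 0.66 over all probes with a value. The SD here was 0.40 over probes above background. In the authors' deposited values 344 probes reached a departure of 1, so a bound of 1 is easier to pass there and does not decide about the offset. A wider scale of the combined array as a whole also stays open. When the sum was multiplied by 1.54, the ratio of SDs between arrays, 76.5% kept a departure of at least 1. The sum had a median of 0.06, and multiplying hardly changes a sum near 0, so this share does not decide. A response to both treatments that exceeds their sum is among the open explanations, and as above the treated RNA of 1 array carries it.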

How the results depend on the processing

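The added setting, local background subtraction, and the counts in both estimates and against each single treatment were chosen after the data were seen. Counts in each of 9 alternatives were set against the main ones, a move being a change by over 1.5 times. Without a filter on dim probes, and with a filter on both channels, no count of probes moved; the departure already used both channels. Without background correction, probes higher were 231 for IL-22 under Hes1 and 219 for both against each alone, probes lower were 68 for both and 5 for IL-22 under Hes1, and 71 were higher in both estimates for Hes1. At an offset of 16, probes higher were 57 for IL-22, 153 for Hes1, 769 for both, 267 for IL-22 under Hes1, 541 for Hes1 under IL-22 and 246 for both against each alone. Probes lower were 85 for both, 12 for IL-22 under Hes1, 45 for Hes1 under IL-22, 4 for both against each alone and 191 for the departure. Higher in both estimates were 11 for IL-22 and 85 for Hes1. A lower offset compresses the ratios of dim probes less.

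Under median centring, probes higher were 153 for IL-22, 246 for Hes1 and 82 for the departure. Probes lower were 6 for IL-22 under Hes1, 57 for Hes1 under IL-22, 6 for both against each alone and 752 for the departure, whose median over all probes moved to -0.17. In both estimates, Hes1 had 85 higher and 1 lower. The authors' deposited values gave probes higher of 178 for IL-22, 367 for Hes1, 1243 for both, 518 for IL-22 under Hes1, 846 for Hes1 under IL-22, 427 for both against each alone and 344 for the departure. Probes lower were 41 for IL-22, 47 for Hes1, 302 for both, 64 for IL-22 under Hes1, 207 for Hes1 under IL-22, 28 for both against each alone and 374 for the departure. In both estimates, IL-22 had 29 higher and 2 lower, and Hes1 had 224 higher and 16 lower. The share of higher probes was 80.3% in place of 94.1% for Hes1 under IL-22, and 47.9% in place of 58.0% for the departure.

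At a threshold of 1.5-fold, probes higher were 379 for IL-22, 582 for Hes1, 1536 for both, 597 for IL-22 under Hes1, 1055 for Hes1 under IL-22, 558 for both against each alone and 670 for the departure. Probes lower were 54 for IL-22, 99 for Hes1, 517 for both, 77 for IL-22 under Hes1, 391 for Hes1 under IL-22, 61 for both against each alone and 926 for the departure. In both estimates, IL-22 had 24 higher and 2 lower, and Hes1 had 202 higher and 27 lower. At 3-fold, probes higher were 7 for IL-22, 3 for Hes1, 144 for both, 30 for IL-22 under Hes1, 105 for Hes1 under IL-22, 25 for both against each alone and 25 for the departure. Probes lower were 3 for IL-22, 2 for Hes1, 8 for both, 1 for IL-22 under Hes1, 1 for Hes1 under IL-22, 1 for both against each alone and 5 for the departure. In both estimates, Hes1 had 2 higher and 0 lower. With the local background subtracted, probes higher were 270 for IL-22, 175 for Hes1, 308 for IL-22 under Hes1 and 332 for the departure. Probes lower were 92 for IL-22 under Hes1, 222 for Hes1 under IL-22, 24 for both against each alone and 529 for the departure. In both estimates, IL-22 had 66 higher and 1 lower. Except for thresholds and the offset, the cause was not tested.

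Of the 7 probes higher with IL-22 in both estimates, all stayed so without background correction, at an offset of 16, under median centring and without a filter. With the authors' values, a filter on both channels and the local background, 6 of them did. Of the 43 for Hes1, the settings other than thresholds shared between 21 (local background) and 43, and of the 138 higher than after each treatment alone, between 72 (local background) and 138. Of 188 values of named probes past 2-fold, recomputed under other corrections, none changed sign, which would have needed a shift of at least 1 on the log2 scale. Of the smaller second estimates printed for named probes, those of DHsGV10004900 and H200003125 for IL-22 did, to 0.27 and 0.35 with the local background subtracted. By over the mean SD between control channels (0.11), 106 moved further from 0 and 37 nearer to it. No leave-one-out was possible with 1 array per condition. The brightest probe of a gene against the mean of its probes, and the medians of gene lists, were not run because probes had no gene names. No paired analysis was possible because each condition had 1 array. Dim control signals leave ratios without a fold, as for H200000879 with IL-22.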

Other observations

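Positive Control 2 spots, 24 on each array, had mean treated signals of 26919 with IL-22, 25328 with Hes1 and 14935 with both, and mean control signals of 16563, 15419 and 14966. Positive Control 1 spots had 49039, 46148 and 39414 in the treated channel and 44673, 43247 and 43092 in the control channel. The sources used here do not say which sequence these spots hold.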
